A study of Bos taurus with 12 samples.

How the data were processed

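The data were 12 two-colour Agilent arrays of the bovine EmbryoGENE probe set, each with 1 pool of blastomeres in Cy5 and 1 in Cy3. Per the labels' protocols, total RNA of 3 independent pools of 15 blastomeres per class was amplified and labelled with a chemistry that binds dye to guanine. The authors deposited 1 log ratio per probe and array, and limma is named in the submitters' processing notes without a version. The log base is not stated and was taken as log2, as in limma. Background correction, normalization within arrays and filters are not given in the sources used here, and scanner intensities were not used here. Columns of the deposited log2 ratios had medians of -0.003, 0.000 and 0.010 (2CB in Cy5, BL in Cy3, replicates 1 to 3), 0.000, 0.004 and -0.001 (BL in Cy5, 2CB in Cy3), 0.002, 0.005 and -0.001 (8CB in Cy5, BL in Cy3) and -0.002, 0.001 and -0.003 (BL in Cy5, 8CB in Cy3). They were thus centred, with SDs from 0.26 to 0.38, and the direction of the ratio stayed unknown. Without intensities, no probe could be said to lie above background, and the number of arrays limits the precision.

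Of 43795 rows, 1 with a missing value and 1 outside the numbered probes were left out. The annotation table gave 1 symbol for 21790 probes and several for 0, and 22005 rows were unnamed here. Against the gene names of assembly ARS-UCD2.0, 20068 probes had a current symbol, 1644 had an older symbol that was updated, and 78 had an older symbol of several genes, which was kept. No coordinates are given, since the array's build is not named.

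The 2 dye-swapped arrays of one replicate number were averaged, and 6 averaged ratios (3 per comparison) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 coefficient per comparison and a shared spread. P-values were two-sided and adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. The difference between arrested classes was the contrast of both coefficients. The plan, fixed before the data were examined, was to turn all ratios to BL over the arrested class, and to check whether swapped arrays had already been turned. That check led to averaging the values as deposited, which departs from the labelled dyes; the count of calls with the dyes turned is given beside each main count of calls. Under the deposited reading a dye effect enters both orientations with opposite sign and cancels in the average.

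Deviations of the averaged ratios from their group means correlated between comparisons for the same replicate number, at 0.30, 0.39 and 0.35, and each ratio correlated best with its own number. By this measure the numbers pair the samples across comparisons; the labels do not say which pools the comparisons share. For number 3 of BL against 8CB, the deviations of the dye-swapped arrays correlated negatively (r = -0.22), so that they hold the same pools was assumed. The random block was the replicate number within each comparison, and the consensus correlation of its swapped arrays was 0.24.

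The 20 gene lists were fixed before the data were examined. They were tested on 1 value per gene, the mean of its probes, with camera at a preset correlation of 0.01 and adjustment over the lists of a comparison. No list was called, so none could be lost with an estimated correlation, where the smallest adjusted p was 0.99. Lists overlapped by at most 4 genes. Named genes were chosen by a rule fixed in advance: per comparison and side, 1 probe per gene with the smallest p, on one side in all 3 replicates, past the threshold where any were. As none were, 6 per side (5 between arrested classes) are given as values. For each list of the direct comparisons, up to 4 genes past the threshold over the list alone are named, or else the 2 with the smallest p, and 10 redox genes are always given.

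The fit was tested on simulated data for BL against 2CB with 43793 probes and 200 changed. Of 100 probes changed by 0.5 on the log2 scale, 56 were called at an adjusted p under 0.05, and of 100 changed by 1, 84 were called, with 10 unchanged probes called. The noise was normal, independent between probes, and took each probe's estimated residual variance as its true variance. Such estimates vary more than the true variances, so the counts can overstate the power in the data. Alternatives were the replicate block and independent arrays (both over 12 arrays with a dye coefficient), each dye orientation, separate fits, median centring, scaling, quantile normalization, robust moderation, a filter on small ratios, other thresholds, and each replicate left out. The turn by the labelled dyes, planned at first, became an alternative after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.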

Results

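The transcripts of single blastomeres from 2-cell bovine embryos were compared according to what became of the sister cell. Each embryo was bisected, one blastomere was cultured on its own and the other was frozen. The frozen cells were pooled by the fate of their sisters at day 7. BL denotes sisters that reached the blastocyst stage, and 2CB denotes sisters that did not cleave after separation. The third class is named 8CB in the labels, although the same labels describe its sisters as stopping at 4 cells, so only the name 8CB is used here. RNA came from 3 independent pools of 15 blastomeres per class and was amplified. BL was hybridised against 2CB on 6 arrays and against 8CB on 6 arrays, in both dye orientations, with replicate numbers 1 to 3. In total 43793 probes were tested, of which 21790 carried a gene symbol, for 15214 genes. The number of arrays limits the precision, since each comparison rested on 3 averaged ratios.

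Which class forms the numerator of the deposited ratios was not settled by the labels, so no direction from BL to the arrested classes is given for them. If the values were still Cy5 over Cy3, dye-swapped arrays of one replicate number, which are taken to share their pools, would deviate from their group means in opposite directions. As deposited, they deviated in the same direction in 5 of 6 pairs, with a median r of 0.38 across probes. The exception was replicate 3 of BL against 8CB, at -0.22. The difference between the comparisons also repeated with the same sign in both orientations (r = 0.55 across probes, which are not independent replicates). The swapped arrays were therefore treated as already turned to one direction and averaged as deposited, a choice made after these values were seen. Values are described by the positive or the negative side of the deposited ratio, on the assumption that both comparisons were turned alike. Counts at an adjusted p under 0.05 with the sign turned by the labelled dyes are given beside them, and those at other thresholds in the last paragraph.

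**Figure D1:**
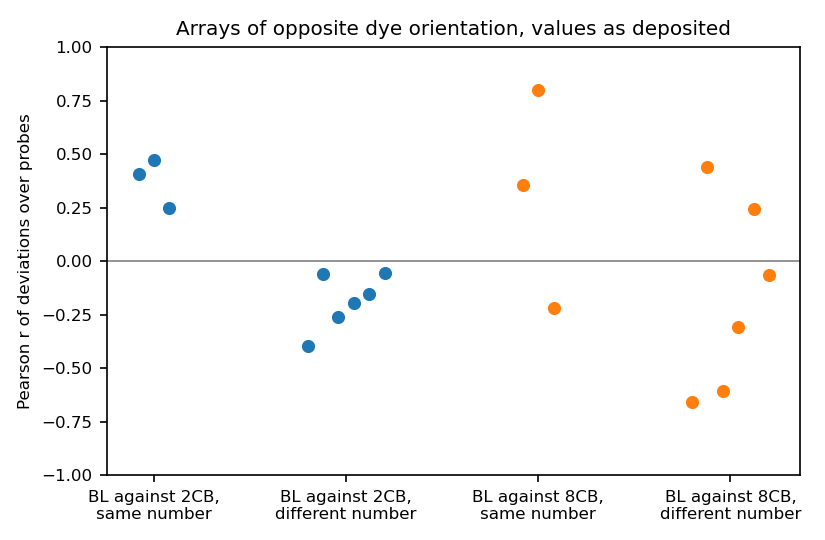
Pearson r over probes (y axis) between the deviations from their group means of arrays of opposite dye orientation, for pairs of the same and of different replicate numbers (x axis; each point is 1 pair of arrays, 3 same-number and 6 different-number pairs per comparison). The 3 same-number pairs of BL against 2CB lie between 0.25 and 0.47, and those of BL against 8CB at 0.36, 0.80 and -0.22; deviations within groups of 3 sum to 0, which lowers the values for different numbers.

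BL against 2CB asks which transcripts at the 2-cell stage differ between cells whose sisters formed blastocysts and cells whose sisters never divided. The smallest p-values on the negative side belonged to RWDD4 at -0.71 ± 0.04 (log2, SE, n = 3), CHURC1 at -0.60 ± 0.04 and GSTCD, a protein with a glutathione S-transferase domain, at -0.47 ± 0.03. They were followed by the R-spondin receptor LGR4 at -0.88 ± 0.07, the retromer subunit VPS26A at -0.79 ± 0.06 and the deubiquitinase BRCC3 at -0.80 ± 0.07. On the positive side stood the centriolar protein POC1A at 0.74 ± 0.06, the exocyst subunit EXOC8 at 0.36 ± 0.03, C7H1orf35 at 0.80 ± 0.08 and the polarity scaffold LIN7B at 0.52 ± 0.05. AKR1B1, an aldo-keto reductase, lay at 1.05 ± 0.11, a 2.07-fold difference, and the splicing factor SFPQ at 0.53 ± 0.06. All 12 had to keep one side in 3 of 3 replicates to be named. Their adjusted p-values in limma lay between 0.064 and 0.076, so none passed 0.05. At least 1 other probe of the gene lay within 0.10 of 0 for LGR4 (3 probes, -0.88 to 0.01), BRCC3 (2, -0.80 to 0.04), LIN7B (5, 0.05 to 0.52) and C7H1orf35 (3, 0.07 to 0.80).

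Over all probes limma called 0 at an adjusted p under 0.05 in BL against 2CB. At an adjusted p under 0.10 it called 336, of which 237 lay on the negative side and 99 on the positive side. An unadjusted p under 0.05 was reached by 7249 probes (16.6%), where 2190 are expected without any difference, and 922 of them also differed at least 1.5-fold. One side was kept in all 3 replicates by 43.1% of probes, where 25% is expected by chance. With the 12 arrays entered singly, a coefficient for the dye and the replicate number within each comparison as a random block, 2492 probes passed 0.05. With the sign turned by the labelled dyes, 3562 passed.

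**Figure D2:**
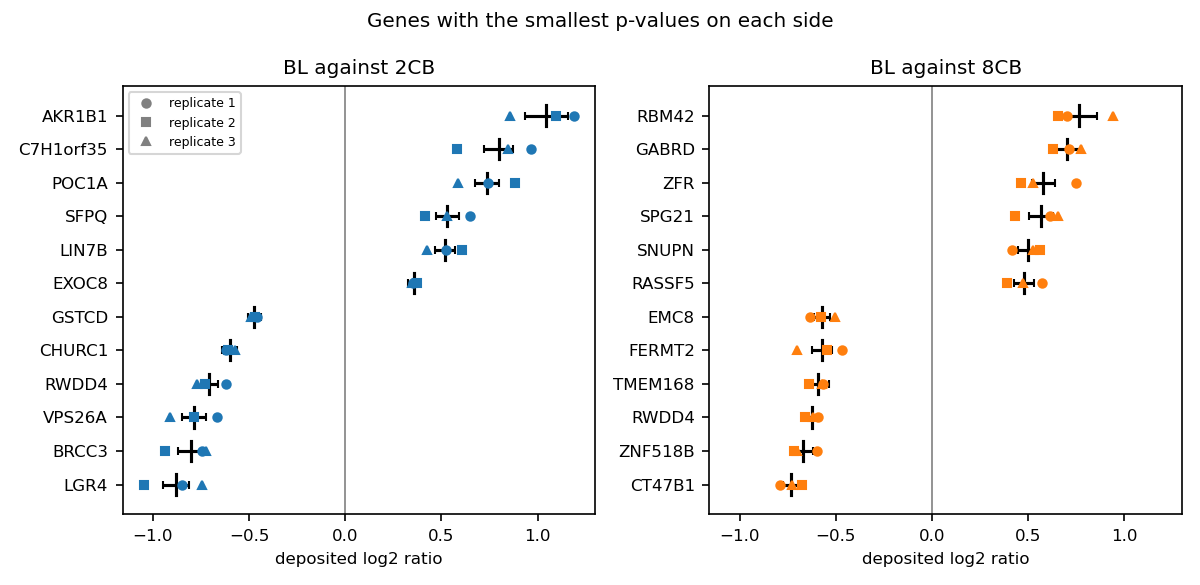
Deposited log2 ratios (x axis) of the genes with the smallest p-values on each side (y axis), for BL against 2CB and BL against 8CB. Symbols are the averaged ratios of replicates 1 to 3, the vertical tick is the fitted mean and the bar its SE; RWDD4 appears in both panels, at -0.71 and -0.62.

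None of the 20 gene lists shifted as a whole in BL against 2CB by camera. By the mixed test of fry, which asks whether members change in either direction and compares them with no other genes, 13 of 20 had an adjusted p under 0.05, with genome activation at 0.0009 and sperm and testis markers at 0.022. Yet only 5 of 33 genome activation genes (15.2%) and 1 of 20 sperm and testis markers (5%) reached an unadjusted p under 0.05, against 18% of all genes. The smallest adjusted p by camera was 0.062, for DNA damage response and repair, with a median of -0.08 and 39 of 57 measured genes on the negative side. Adjusted over the list alone, 6 of its genes passed, 5 of them on the negative side. These included the BRCA2 partner PALB2 at -0.48 ± 0.07, the replication protein RPA2 at -0.41 ± 0.08 and the p53 inhibitor MDM4 at -0.48 ± 0.10, whereas DNA ligase LIG1 lay at 0.69 ± 0.12. No gene of any list passed over all genes tested. Oocyte and maternal-effect genes had a median of 0.08 (adjusted p = 0.12), led by the oocyte linker histone H1-8 at 0.69 ± 0.17 and the meiotic kinase MOS at 0.51 ± 0.13, and 0 of 47 passed over the list alone.

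Translation factors held the most genes that passed over the list alone, 13 of 44, and these went both ways (9 positive, 4 negative; adjusted p of the list 0.88). EIF4H lay at 0.76 ± 0.14, the release factor GSPT1 at 0.72 ± 0.12 and EIF5A at 0.37 ± 0.07, while EIF3E lay at -0.63 ± 0.10. In cell cycle and mitosis, 9 of 92 passed over the list alone, among them the repressor E2F4 at 0.44 ± 0.05, the spindle checkpoint protein MAD2L2 at 0.52 ± 0.09, the anaphase-promoting complex activator FZR1 at 0.44 ± 0.08 and its subunit ANAPC4 at -0.59 ± 0.09. Of mitochondrial oxidative phosphorylation, 6 of 75 passed: complex I held NDUFS8 at 0.40 ± 0.08 but NDUFS1 at -0.55 ± 0.11 and NDUFB6 at -0.36 ± 0.07, and SDHC of complex II lay at 0.37 ± 0.08. The proteasome subunits PSMC3 (0.57 ± 0.08) and PSMD4 (0.36 ± 0.05) passed over their list, as did the mRNA decapping factor DCP1A (-0.30 ± 0.05), CPEB3 (-0.33 ± 0.05), the chaperones HSPA2 (0.55 ± 0.08) and HSPA4 (-0.57 ± 0.09), and the apoptosis regulators BIRC6 (-0.30 ± 0.06) and CASP8 (-0.37 ± 0.07). The histone methyltransferase SETD1A at -0.52 ± 0.07 and TAF4 at -0.54 ± 0.09 were the single such genes of the chromatin and the genome activation lists.

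No gene passed over the list alone among cytosolic ribosomal proteins (64 measured; RPS15 at 1.11 ± 0.27 and RPL3 at 0.57 ± 0.14), pre-mRNA splicing (62; SRSF9 at 0.37 ± 0.06 and U2AF2 at 0.50 ± 0.10) or glycolysis and the pentose phosphate pathway (30; PGAM1 at -0.55 ± 0.13 and PDHA1 at -0.18 ± 0.05). The same held for fatty acid oxidation and lipid storage (42; FABP3 at 0.31 ± 0.07 and ETFDH at -0.31 ± 0.08) and for blastocyst lineage markers (28; KRT8 at 0.63 ± 0.17 and KRT19 at 0.60 ± 0.18). Markers of other cells had the lowest shares of the 20 lists. An unadjusted p under 0.05 was reached by 1 of 36 cumulus and granulosa markers (INHBA at 0.30 ± 0.08, with FST at -0.15 ± 0.07), 1 of 20 sperm and testis markers (ZPBP at -0.40 ± 0.16, with PGK2 at 0.13 ± 0.07) and 0 of 18 blood and immune markers (CD8A at 0.07 ± 0.04 and MS4A1 at 0.07 ± 0.05).

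**Figure D3:**
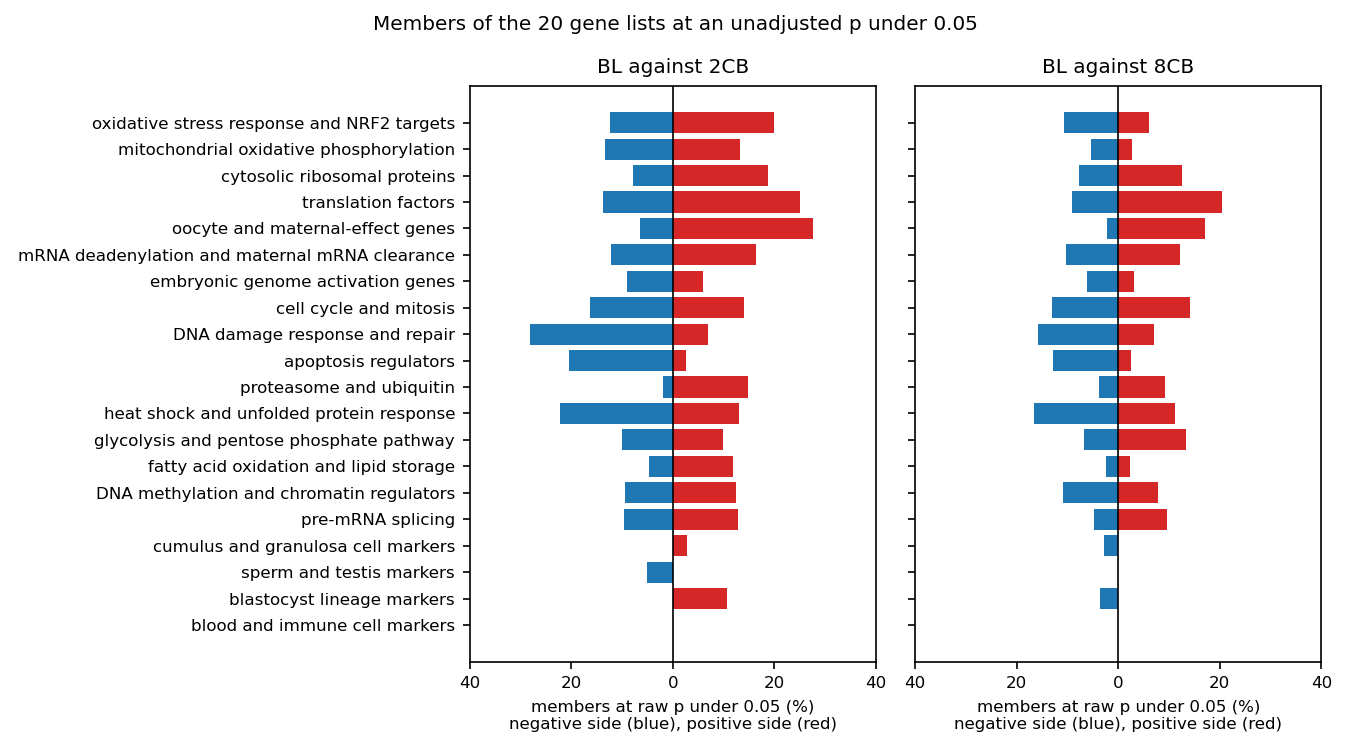
Share of measured members (x axis, percent) of each of the 20 gene lists (y axis) at an unadjusted p under 0.05, on the negative side (blue, leftward) and the positive side (red, rightward). DNA damage response and repair shows 16 negative against 4 positive members in BL against 2CB, and no list passed camera in either comparison.

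BL against 8CB asks the same of cells whose sisters divided and then stopped. On the negative side the smallest p-values belonged to CT47B1 at -0.73 ± 0.04 (log2, SE, n = 3), RWDD4 at -0.62 ± 0.04, the membrane protein complex subunit EMC8 at -0.57 ± 0.04, ZNF518B at -0.67 ± 0.06, the integrin adaptor FERMT2 at -0.57 ± 0.05 and TMEM168 at -0.59 ± 0.06. On the positive side they were GABRD, a subunit of a GABA receptor, at 0.70 ± 0.07, the RNA-binding proteins ZFR at 0.58 ± 0.06 and RBM42 at 0.77 ± 0.09, RASSF5 at 0.48 ± 0.05, the snRNP import adaptor SNUPN at 0.50 ± 0.06 and SPG21 at 0.57 ± 0.06. Each had to keep one side in 3 of 3 replicates to be named, and their adjusted p-values in limma lay from 0.083 to 0.099. Other probes of the gene went to the opposite side for FERMT2 (4 probes, -0.57 to 0.40). At least 1 lay within 0.10 of 0 for RASSF5 (3, -0.005 to 0.48), SPG21 (2, 0.03 to 0.57), TMEM168 (3, -0.59 to -0.04) and RWDD4 (3, -0.62 to -0.08).

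Over all probes of BL against 8CB, limma called 0 at an adjusted p under 0.05 and 92 at 0.10, of which 70 lay on the negative side. An unadjusted p under 0.05 was reached by 4285 probes (9.78%), and 248 of these differed at least 1.5-fold. One side was kept in all 3 replicates by 27.7%, near the 25% of chance. Averaged ratios of replicates 1 and 2 correlated at -0.209 across probes, those of 1 and 3 at 0.315 and those of 2 and 3 at 0.383. The fit of 12 arrays with a dye coefficient and the replicate number within each comparison as a random block called 798. The values turned by the labelled dyes gave 2028. Without replicate 3 the share at an unadjusted p under 0.05 was 4.57%, and in BL against 2CB it was 8.76%.

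By the mixed test of fry, 8 of 20 lists passed in BL against 8CB, cell cycle and mitosis with the smallest adjusted p (0.0026). No list passed camera, with a smallest adjusted p of 0.25 for oocyte and maternal-effect genes (median 0.08; NLRP9 at 0.30 ± 0.08 and CNOT6L at 0.12 ± 0.04). Translation factors again had the most genes past 0.05 over the list alone, 8 of 44, with EIF4B at 0.92 ± 0.18 and EEF1G at 0.46 ± 0.09 on one side and EIF4G3 at -0.20 ± 0.04 and EIF3E at -0.46 ± 0.10 on the other. Of the cell cycle list 4 of 92 passed: E2F4 at 0.42 ± 0.05, its partner TFDP1 at -0.50 ± 0.07, the kinase PLK2 at -0.54 ± 0.08 and cyclin B1, CCNB1, at -0.47 ± 0.08. SETD1A lay at -0.72 ± 0.07 and the deacetylase HDAC1 at 0.74 ± 0.11, both past the threshold over the chromatin list. UQCRQ of respiratory complex III, at -0.57 ± 0.05, and the polyadenylation endonuclease CPSF3, at -0.54 ± 0.08, were the single such genes of their lists.

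The remaining lists of BL against 8CB had 0 genes past 0.05 over the list alone. Their members with the smallest p-values were MDM2 (-0.36 ± 0.06) and TOPBP1 (-0.27 ± 0.06) for DNA damage, TAF4 (-0.39 ± 0.09) and CTCF (-0.42 ± 0.11) for genome activation, and AIFM1 (0.44 ± 0.12) and MCL1 (-0.21 ± 0.06) for apoptosis. PSMC3 (0.39 ± 0.08) and PSMD11 (0.33 ± 0.07) led the proteasome list, EDEM1 (-0.22 ± 0.05) and HSP90AB1 (0.41 ± 0.10) the chaperones, and RPL3 (0.66 ± 0.14) and RPL11 (0.56 ± 0.13) the ribosomal proteins. Splicing had SRSF9 (0.33 ± 0.06) and SF3B2 (0.49 ± 0.10), glycolysis TALDO1 (0.18 ± 0.04) and PGAM1 (-0.45 ± 0.13), fatty acid oxidation FABP3 (0.22 ± 0.07) and ACSL1 (-0.16 ± 0.06), and blastocyst lineage CDH1 (-0.25 ± 0.09) and KRT19 (0.28 ± 0.18). Among markers of cumulus and granulosa cells (CYP11A1 at -0.16 ± 0.05, COL1A2 at -0.14 ± 0.07), sperm (TNP1 at 0.08 ± 0.04, PGK2 at 0.13 ± 0.07) and blood cells (CD3E at -0.16 ± 0.08, ITGAM at 0.07 ± 0.04), 1 of 74 genes reached an unadjusted p under 0.05, against 11% of all genes.

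The series title names the oxidative stress response, so that list is not independent evidence of its own direction. In BL against 2CB, 21 of its 65 measured genes (32.3%) reached an unadjusted p under 0.05, against 18% of all genes. This share was not particular to the list. It was larger for translation factors (38.6%), heat shock and unfolded protein response (35.2%), DNA damage response and repair (35.1%) and oocyte genes (34%). Of the 21, 13 lay on the positive and 8 on the negative side, and the list did not shift as a whole by camera (median 0.03, adjusted p = 0.88). In the mixed test of fry, passed by 13 of 20 lists, its adjusted p was 0.013. Over the list alone 3 genes passed: AKR1B1 at 0.81 ± 0.09 as the mean of its probes, the mitochondrial glutaredoxin GLRX2 at -0.52 ± 0.09 and sulfiredoxin, SRXN1, at -0.33 ± 0.06. Catalase (CAT) lay at -0.62 ± 0.16 and mitochondrial superoxide dismutase SOD2 at -0.28 ± 0.08, on the same side in 3 of 3 replicates and past no adjusted threshold. In BL against 8CB, 11 genes of the list (16.9%) reached an unadjusted p under 0.05, against 11% of all genes. Lists with larger shares included translation factors (29.5%), heat shock and unfolded protein response (27.8%) and cell cycle and mitosis (27.2%). Over the oxidative stress list alone 0 passed (smallest p for AKR1B1, at 0.48 ± 0.09 as the mean of its probes). Its median was 0.01 (adjusted p = 0.98 by camera and 0.0505 by the mixed test of fry).

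Of the redox genes fixed in advance, CAT and PRDX1, a peroxiredoxin, had the lowest deposited ratios in BL against 8CB, at -0.79 ± 0.16 and -0.65 ± 0.13, both negative in 3 of 3 replicates (adjusted p = 0.21 and 0.22 in limma). SOD2 (-0.22 ± 0.08) and thioredoxin, TXN (-0.21 ± 0.08), were also negative in 3 of 3. NFE2L2, which encodes the transcription factor NRF2, spread from -0.74 to 0.85 between replicates there, and SOD1 from -0.91 to 0.52 as the mean of its 2 probes. With the sign turned by the labelled dyes, BL over 8CB was -0.096 ± 0.041 for CAT, -0.035 ± 0.077 for PRDX1, -0.315 ± 0.058 for NFE2L2 (adjusted p = 0.034) and 0.254 ± 0.045 for GPX1 (0.032; 0.240 and 0.029 over 2CB). Against 2CB, as deposited, PRDX1 lay at -0.22 ± 0.13, TXN at -0.22 ± 0.08, NFE2L2 at -0.53 ± 0.27, SOD1, as the mean of 2 probes, at -0.60 ± 0.29 and GPX4 at 0.30 ± 0.11. Each of these kept one side in 3 of 3 replicates, with TXN at -0.0004 in replicate 3. The SE of NFE2L2 rests on a spread shared by both comparisons. The SD of its replicates was 0.15 against 2CB and 0.79 against 8CB. In BL against 2CB, TXNRD1 lay at 0.26 ± 0.11 by one probe and at 0.13 ± 0.06 as the mean of its 2 probes, the other being at -0.01. Against 8CB, GPX4 lay at 0.02 ± 0.11 and TXNRD1 at -0.02 ± 0.06 as the mean of its probes. GPX1 lay at 0.11 ± 0.06 against 2CB and 0.02 ± 0.06 against 8CB, and the NRF2 inhibitor KEAP1 at -0.06 ± 0.06 and -0.08 ± 0.06.

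**Figure D4:**
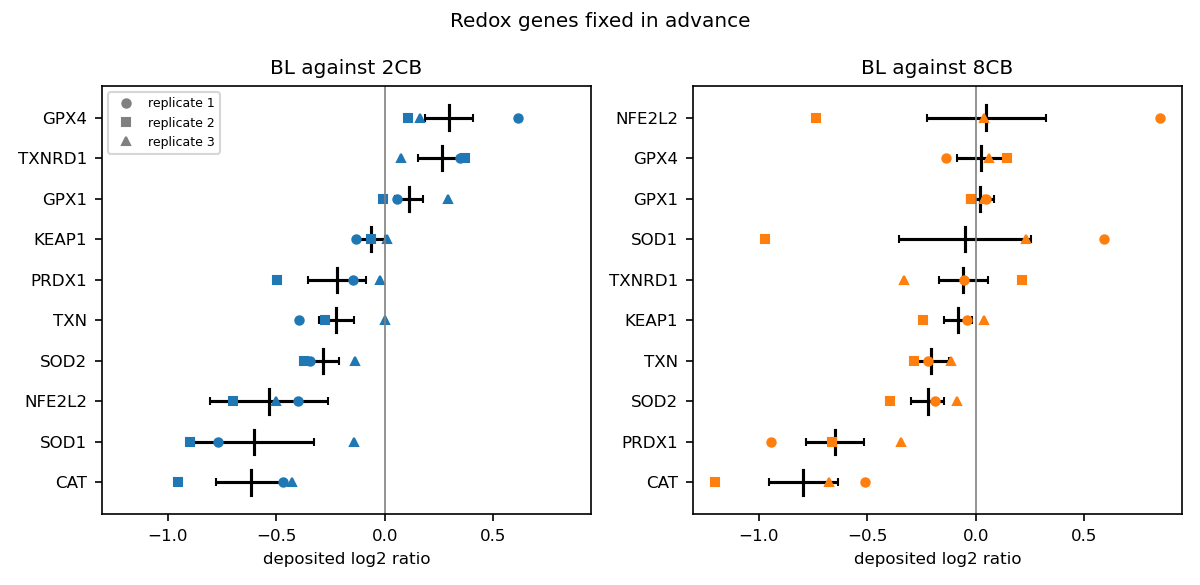
Deposited log2 ratios (x axis) of 10 redox genes (y axis) for BL against 2CB and BL against 8CB. Symbols are replicates 1 to 3, ticks and bars are the fitted mean and SE; CAT is negative in every replicate of both comparisons, while NFE2L2 and SOD1 (1 probe, not the same in both panels) span 0 in BL against 8CB.

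2CB and 8CB shared no array and were compared through BL, as the ratio against 2CB minus the ratio against 8CB. The genes with the smallest p-values were RASSF5 at -0.69 ± 0.07 (log2, SE, n = 3), the mitochondrial ribosomal protein MRPS22 at -0.48 ± 0.05, the bicarbonate transporter SLC4A7 at -0.36 ± 0.05, GSTCD at -0.34 ± 0.05 and TEPP at -0.58 ± 0.09. On the other side were the interferon receptor IFNAR1 at 0.61 ± 0.08, UQCRQ at 0.52 ± 0.08, CHN2 at 0.58 ± 0.09, NUDCD1 at 0.41 ± 0.07 and PPP1R35 at 0.37 ± 0.07. All had an adjusted p of 0.94 in limma, and the smallest over all probes, 0.499, belonged to a probe not named here. Of the other probes of the gene, 1 lay on the opposite side for IFNAR1 (3 probes, -0.14 to 0.61), CHN2 (3, -0.02 to 0.58), NUDCD1 (3, -0.03 to 0.43) and SLC4A7 (3, -0.36 to 0.03), and 1 or more within 0.10 of 0 for RASSF5 (3, -0.69 to -0.02) and TEPP (3, -0.58 to -0.05). The count was 0 at an adjusted p under 0.05 and 0 at 0.10, with 1985 probes (4.53%) at an unadjusted p under 0.05 and 138 of these at least 1.5-fold apart. That share was 7.80% without replicate 2 and 1.84% without replicate 3. With the sign turned by the labelled dyes, 0 were called and 423 probes (0.966%) reached an unadjusted p under 0.05. The main contrast did not use the replicate numbers as pairs. The paired fit, with the replicate number as a block, also called 0, with 9.82% at an unadjusted p under 0.05, above the 4.53% of the unpaired contrast. One side was kept in all 3 replicates by 33.8% of probes, where 25% is expected by chance. No list passed (smallest adjusted p = 0.98), and UQCRQ alone passed over its list. The effects in the 2 comparisons were thus not shown to differ for any single probe at an adjusted p under 0.05. The shares in the paired fit and on one side leave open a difference spread over many probes.

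The fold changes of the 2 comparisons correlated at r = 0.61 across probes. Both comparisons used BL pools, probably the same 3. Simulated classes with no effect, with a shared BL pool supplying 50% of the variance, gave r = 0.50. The same sign was seen for 63.6% of probes, against 66.7% on average in the simulation. At the simulated 50%, equal signs thus showed no agreement beyond shared pools. Deviations of the same replicate number correlated at 0.30, 0.39 and 0.35 between the comparisons, below that setting. Lower settings were not simulated, so the equal signs do not decide it. The covariance was 0.0197 against 0.0075 in the simulation, which leaves 0.0122. The share of 50% was assumed, and 3 pools are too few to split, so part of the excess can still come from the shared pools. If the replicate numbers mark the pools, ratios of different numbers share no BL pool. Their mean covariance was 0.0147, against 0.0298 for the same number, so by this mean some covariance remained without a shared pool. Between ratios of different replicate numbers the mean r was 0.21. It ran from -0.16 (replicate 2 against 2CB with replicate 1 against 8CB) to 0.51 (replicate 3 against 2CB with replicate 2 against 8CB). Without replicate 2, r was 0.26. At an adjusted p under 0.10, 44 probes were shared on the negative side and 10 on the positive side, and 0 were called with opposite signs. Independent lists would share 0.38 and 0.05. The top probes of the simulated classes with no effect, in lists of the same lengths, shared 26.2 and 8.15 on average and at most 34 and 12 in 20 simulations, so at the assumed share the pools alone reached the overlap on the positive side and not that on the negative side.

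The alternative reading, values as Cy5 over Cy3, gives a direction from BL to the arrested classes. It called 2028 probes higher and 1534 lower in BL than in 2CB, 1339 higher and 689 lower than in 8CB, and 0 between the arrested classes. At an adjusted p under 0.10 it called 7712 against 2CB (3664 higher, 4048 lower) and 5297 against 8CB. An unadjusted p under 0.05 was reached by 12789 (29.2%) and 10990 (25.1%), of which 413 (379 higher, 34 lower) and 257 (236 higher, 21 lower) differed at least 1.5-fold. Of the 3562 and 2028 calls at an adjusted p under 0.05, 1651 were shared, 1182 higher and 469 lower in BL and 0 of opposite sign. Lists of the same lengths from classes with no effect against shared BL pools overlapped by 490 and 271 on average, with 27.4 of opposite sign, and a dye effect would also be shared. The genes called in both with the largest ratios, listed after their values were seen, were the N-acetyltransferase subunit NAA35 (1.86 ± 0.11 over 2CB and 1.61 ± 0.11 over 8CB), ACAA2 of mitochondrial fatty acid oxidation (1.70 ± 0.18 and 1.44 ± 0.18), NHERF2, ZNF395 and FGFR4. The lowest were TRIM6 (-1.13 ± 0.12 and -0.74 ± 0.12), UHRF2 (-0.99 ± 0.13 and -0.78 ± 0.13), PDIA6, PARP12 and ARIH2. If the deposited values were already turned, this component is the dye effect and no class difference.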

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

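The counts of 0 probes at an adjusted p under 0.05 stayed at 0 in all 3 comparisons with BL in Cy3 alone, median centring, scaling, quantile normalization, robust moderation, the filter on small ratios and each replicate left out, and in both direct comparisons fitted alone; the separate fit was not run for the arrested classes, which need both. They rose in the fits below, and the cause was not tested. Under the deposited reading, a single orientation does not cancel a dye effect. The fits of 12 arrays enter both swapped arrays of a number as observations. The random block allows for their correlation with 1 consensus value (0.24) for all probes, and the fit of independent arrays does not. The higher counts were not read as class differences. With 12 single arrays, a dye coefficient and the replicate number within each comparison as a random block, BL against 2CB gave 2492 and BL against 8CB 798. With the dye coefficient and arrays as independent, the counts were 3826, 1386 and, between arrested classes, 7. With BL in Cy5 alone they were 4220 and 1407. With the sign turned by the labelled dyes, the planned turn that became an alternative after seeing the data, they were 3562 and 2028. Looser thresholds gave 336 and 92 (adjusted p under 0.10) and 922, 248 and 138 (unadjusted p under 0.05 with at least a 1.5-fold difference). Neither block changed a count between arrested classes, though only the paired block joins the ratios of one number across comparisons. The paired block changed no list call there, and no blocked list test was run for the direct comparisons. The correlation of the comparisons was 0.21 between different replicate numbers and lay between 0.26 and 0.71 with 1 replicate left out.

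List calls, 0 in camera, remained 0 in the settings run for a shift to one side except with a replicate left out, where BL against 2CB had 0 to 1 and BL against 8CB 1 to 2. Without replicate 1, DNA damage response passed against 2CB (adjusted p = 0.017) and oocyte genes against 8CB (0.032); without replicate 2, proteasome genes (0.023), and without replicate 3, oxidative phosphorylation and ribosomal proteins (0.0049 each), passed against 8CB. With an estimated correlation none of these passed camera, at adjusted p-values from 0.80 to 0.97. No list passed that test with all replicates either (smallest adjusted p = 0.99), and its power was not measured. It therefore does not decide whether these calls hold. Why leaving out a replicate gave calls was not tested.

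The 34 values named for their small p had to lie on one side in all replicates, so leaving one out could not turn them. With the turn by the dyes 15 kept their side; 24 passed 0.05 with the random block. Past a threshold, the sign turned under that reading for NFE2L2 (-0.32) and AIFM1 (-0.22), both in BL against 8CB. Sign changes past no threshold numbered 38 for named genes and 102 for list members. What depth limits was not measurable without signal over background.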

Other observations

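The tests on dye orientation, on replicate numbers and on markers of other cells were chosen after their results had been seen; those on other groupings and on gene families were set beforehand.

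Families of genes with a common symbol root were examined as groups not covered by the fixed lists. Of 107 families with at least 15 measured genes, 0 passed camera at the preset correlation in BL against 2CB. The 2 with the smallest adjusted p (0.14 each) were the cyclin-dependent kinases and related CDK genes, with 7 of 27 at an unadjusted p under 0.05 on the positive side and 1 on the negative, and the centrosomal CEP genes, with 1 of 21 positive and 7 negative. Between the arrested classes 0 passed either, with CDK genes at 0.057 (median 0.11), and in BL against 8CB they lay at 0.99 (median -0.003). Zinc finger ZNF genes had 44 of 247 negative and 15 positive (adjusted p = 0.26). The hypothesis that family members shift together was left open. With an estimated correlation 0 families passed, which met the bound set beforehand against it. However, 0 of the 20 fixed lists passed that test either (smallest adjusted p = 0.99), and its power was not measured. The bound was therefore not taken to decide.

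The deposited values held a component that flips with the dye orientation, and whether it is a dye effect or the class difference decides which genes are of interest. That the values had been turned to one direction before deposit is a candidate explanation, since the difference between the comparisons repeated with the same sign in both orientations (r = 0.55). A hybridisation batch of each number and comparison stays open. For the difference between the comparisons that both orientations share, the r between 2 probes of one gene was 0.222. This was 0.079 above that of the flipping component (bootstrap SE 0.032), but differed by -0.034 from that of the component all arrays share (SE 0.031). Which of these components is the dye effect depends on the reading. The difference between the comparisons that flips with the orientation had an r of 0.055. It also had the smallest variance of these components (0.00211), and no SE was computed for it. A class difference under the labelled dyes stays open, because the swapped pairs had a median r of 0.38 but 1 of 6 lay at -0.22. That pair belongs to the arrays of BL against 8CB whose numbers 1 and 3 may be exchanged. With these numbers exchanged, the r values would be 0.44 and 0.24, so the negative pair is weak evidence for that reading. The flipping component correlated at 0.83 between the comparisons. Both readings allow this, since the comparisons share BL and the dyes. A biological difference between classes is open under both readings.

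More small p-values were seen in BL against 2CB than expected. Values argued against RNA of cumulus or granulosa cells, sperm or blood cells that differed alike in all replicates. Of their 74 markers, 2.70% reached an unadjusted p under 0.05, against 18% of all genes. Such RNA in a single pool would widen the spread and could not be seen this way. No such list shifted by camera, but no list of any kind did. Sperm and testis markers passed the mixed test of fry (adjusted p = 0.022), as did 12 of the other lists. Of the markers, 1 also stands in the blastocyst lineage list, and levels could not be read from ratios. Of 4 sign patterns of the replicates, 1, the real one, gave as many probes in BL against 2CB (7249, highest other 2183) and 1 in BL against 8CB (4285, highest other 3303); 4 patterns are too few for a share under 0.05. Between the arrested classes, 4 of 10 splits gave at least the real 1985, up to 6357, too few splits again for a share under 0.05. The highest points to a structure of the samples that was not identified: the 4 splits with both ratios of replicate 2 together gave 6357, 4859, 2130 and 1464. Among the 4 splits that part all 3 pairs, the real one was the highest, with 1371 next.

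In BL against 8CB with BL in Cy3, the arrays numbered 1 and 3 may have been exchanged in number. They deviated more with the exchanged number than with their own in 2 of 3 sets of arrays, with sums of r of 0.68 against 0.14 and 0.65 against -0.34, and less in the third set (0.047 against 0.28). Those sets do not decide it, no biological explanation was tested, and the numbers were kept as labelled.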
